A study of Mus musculus with 12 samples.

How the data were processed

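Gene expression was measured in lower abdominal muscle of 1-month-old male FVB/N mice on Illumina mouse bead arrays, a platform that hybridises biotin-labelled cRNA to gene probes and reads 1 colour. The 12 arrays fell into 3 groups of 4: wild type (WT) and a pair of humanized aromatase transgenic lines, AromhumL and AromhumH. Aromatase converts androgens to oestrogens, and per the labels its human form was expressed at a lower level in AromhumL and at a higher level in AromhumH. Group and replicate number were taken from the sample titles. The labels do not state that each replicate was a separate animal, so p-values measure the spread between these samples, which may be partly technical.

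Per the labels, RNA was extracted with Trizol, cleaned with a column kit that included DNase treatment, checked on a Bioanalyser and labelled with a kit made for Illumina arrays. Per the file headers, the authors deposited a summary intensity per probe and array on a linear scale, not normalized between arrays. Beside each intensity the deposited table held a detection p-value, which fell as intensity rose on every array. The authors also deposited a table of processed values, on a log2 scale as judged from the values themselves. That table was quantile-normalized, with a median of 7.17, a minimum of 7.03 and a maximum of 14.70 on every array, and its genes were not centred. Each of its columns ranked the probes as the intensities of the same array did (rank correlation 1). It followed log2 intensity at the bright end and was compressed at the dim end, and the transformation and offset behind it are not given in the sources used here. Scanner software, chip position and genome build are not given in the sources used here either, so no slide effect was tested and no coordinates are printed.

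The table held 45281 probes and 0 control probes. Gene symbols came from the platform annotation: 34885 probes had 1 symbol, 18 had several and 10378 had none. Gene numbers matched a current RefSeq gene table for 34807 probes, and 0 symbols needed updating. Probes with several symbols or none were not named.

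The intensities were corrected for background and quantile-normalized with the neqc function of limma 3.58.1 in R 4.3.3. This function estimated the background from the detection p-values and added an offset of 16 before log2 was taken. A probe was kept when its detection p-value was below 0.05 on at least 4 of the 12 arrays, the size of a group. This left 19004 probes. Each gene was represented by its named probe with the highest mean over all arrays, giving 10575 genes, of which 3944 had more than 1 detected probe. Values of other detected probes of a named gene are given where they differed most from the brightest. A probe that was detected on no array of a group has only a bound there. Its fold is then written as "at least", set against the higher, on each array, of the probe's own value and the lowest value among detected probes.

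Group means were fitted to all 12 arrays with lmFit and eBayes of limma, which left 9 residual degrees of freedom and gave 6.53 prior degrees of freedom. AromhumH was compared with WT, AromhumL with WT, and AromhumH with AromhumL. P-values were adjusted over all genes by the Benjamini-Hochberg method, and a gene was called changed at an adjusted p under 0.05. The median standard error of a log2 change was 0.16, set by the number of arrays. Changes are log2 differences of group means, folds are their antilogs, and every adjusted p of a gene comes from limma.

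Before the data were examined, 34 gene lists were fixed: 19 of cellular programmes and 15 of cell type or sex markers. The programme lists covered sex steroid action, matrix, contractile genes, metabolism, growth, interferon, clock and stress genes. Lists of brown adipocyte, lymphocyte and neutrophil markers had fewer than 3 measured members and were not tested, leaving 31. Lists were tested with the camera function of limma at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and the fry function of limma were alternatives. Member counts are given over all genes and adjusted over the list alone.

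The genes named in the text follow a rule fixed at the same time. It takes, per comparison, the 10 largest rises and 10 largest falls among changed genes whose groups did not overlap, skipping clone symbols. Where fewer than 3 genes pass, the 5 with the smallest p are named as not passing. For each list it takes up to 4 changed members, or otherwise the member with the smallest p. Where no list member passed and the list did not shift, these members are given as a range. Esr1, Esr2, Pgr, Greb1, Cyp19a1, Col1a1, Col3a1, Fbxo32, Trim63 and Mki67 are among the genes always included.

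Array measures were compared by two-sided exact permutation tests, which with 4 arrays against 4 cannot give a p below 0.0286. No pair of arrays held identical values, and correlations between arrays of a group ran from 0.977 to 0.988. The fit and threshold were tested on simulated normalized values for AromhumH versus WT, with 200 of 10575 genes changed at 4 arrays a group. A further short list of genes was given a smaller shift. Genes varied independently there, so background correction, normalization and shared variation of genes were not tested. Averaged over 10 simulations, it called 87.7% of genes changed by a log2 of 1 and 98.8% of those changed by a log2 of 2. All called genes among the 200 changed ones had the right direction, and on average 9.3 unchanged genes were called.

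Alternatives covered the background correction, the deposited processed values, 75th percentile scaling, the detection filter, the choice of probe, the samples in the fit, the spread model, array weights, the replicate number as a block, a fold threshold of 1.5 and leaving out each array. Array brightness and the mesothelial marker mean as covariates were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.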

Results

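The series asked what a shift from androgen to oestrogen action does to lower abdominal muscle, using humanized aromatase mice in which human aromatase is lower (AromhumL) or higher (AromhumH). Each group, WT included, had 4 arrays. Between 17198 and 18867 of the 45281 probes were detected per array. Mean raw intensity was 334.7 ± 31.6 in AromhumH, 259.0 ± 25 in AromhumL and 317.9 ± 49.9 in WT (SD, n = 4). AromhumH arrays were brighter than AromhumL arrays (exact permutation p = 0.0286, the smallest possible), whereas neither line was separated from WT (exact permutation p = 0.629 for AromhumH and 0.114 for AromhumL). The leading principal component held 32.2% of the variance and the next 15.9%.

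Of the receptors and enzymes behind the question, Esr1, which encodes oestrogen receptor alpha, was detected on 12 of 12 arrays. Its log2 change was 0.46 (SE 0.282, adjusted p = 0.438 by limma) in AromhumH versus WT and −0.15 (adjusted p = 0.901) in AromhumL versus WT. Probes for Esr2, oestrogen receptor beta, and Pgr, the progesterone receptor, were detected on 0 arrays. Mouse Cyp19a1, which encodes aromatase, and Mki67, a proliferation marker, had no named probe and were not analysed here. A mouse probe need not detect the human transgene.

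In AromhumH muscle compared with WT, 93 genes rose and 32 fell of 10575 tested (limma, adjusted p under 0.05). The largest rise was that of Kiss1, the precursor of the kisspeptins, peptides that stimulate gonadotropin-releasing hormone neurons, at 31.1-fold (log2 4.96, SE 0.858, adjusted p = 0.0145). Kiss1 was detected on 4 of 4 AromhumH arrays and 3 of 4 WT arrays. Its log2 change was 3.18 on the deposited processed values, which are compressed at the dim end, and it did not pass without AromhumH 2 (adjusted p = 0.0598), without AromhumH 4 (adjusted p = 0.0519), without the detection filter (adjusted p = 0.0755) or with the trend and robust options of eBayes (adjusted p = 0.0637). Myh8, the perinatal myosin heavy chain, rose 8.83-fold (log2 3.14, SE 0.660, adjusted p = 0.0341), but passed in only 6 of 12 fits that left out 1 array. Among the fits that left out a WT or AromhumH array, it passed only without AromhumH 1 (adjusted p = 0.0425) and without AromhumH 3 (0.0359). With array brightness as a covariate its adjusted p was 0.0554. It did not pass on the deposited processed values (adjusted p = 0.0815), without background correction (0.0625), without the detection filter (0.129) or with the trend and robust options (0.102). Timp1, an inhibitor of matrix metalloproteinases, rose 4.19-fold (log2 2.07, SE 0.352, adjusted p = 0.0145). Genes of surface epithelia rose with them: Krt8, a keratin of simple epithelia, by 4.38-fold (log2 2.13, SE 0.312), Msln, a surface protein of mesothelial cells, by 3.79-fold (log2 1.92, SE 0.283) and Upk1b, a uroplakin, by 3.57-fold (log2 1.83, SE 0.325).

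The other large rises were those of Emb, which encodes the membrane glycoprotein embigin (log2 2.38), Prr15 (2.20), Lrrc15, a leucine-rich repeat membrane protein (1.81, uncertain because its WT mean of 4.62 lay at the detection floor and it was detected on 1 of 4 WT arrays), and Ankrd1, a stress-responsive ankyrin repeat protein of muscle (1.79). Among the falls, Amd2, an S-adenosylmethionine decarboxylase of polyamine synthesis, fell by 1.78 on the log2 scale (SE 0.399, adjusted p = 0.0427), and its probe may also read the near-identical Amd1. Kcng4 and Kcnab1, which encode potassium channel subunits, had log2 changes of −1.29 and −0.99, and Lrrc38, an auxiliary channel subunit, fell by 0.95. Lrrc30 fell by 1.25, and Gdf10, a secreted member of the TGF-beta superfamily, fell by 1.14. Cpeb4, which binds polyadenylation elements of mRNA, Ganc, a neutral alpha-glucosidase, and Plcd4, a phospholipase C, had log2 changes of −0.92, −0.89 and −0.85. The brightest probe of Ubxn2a fell by 0.98 on the log2 scale while another probe of the gene stood at 0.28. These 20 genes had adjusted p-values between 0.00794 and 0.0427, and all 4 AromhumH arrays lay on one side of all 4 WT arrays.

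**Figure D1:**
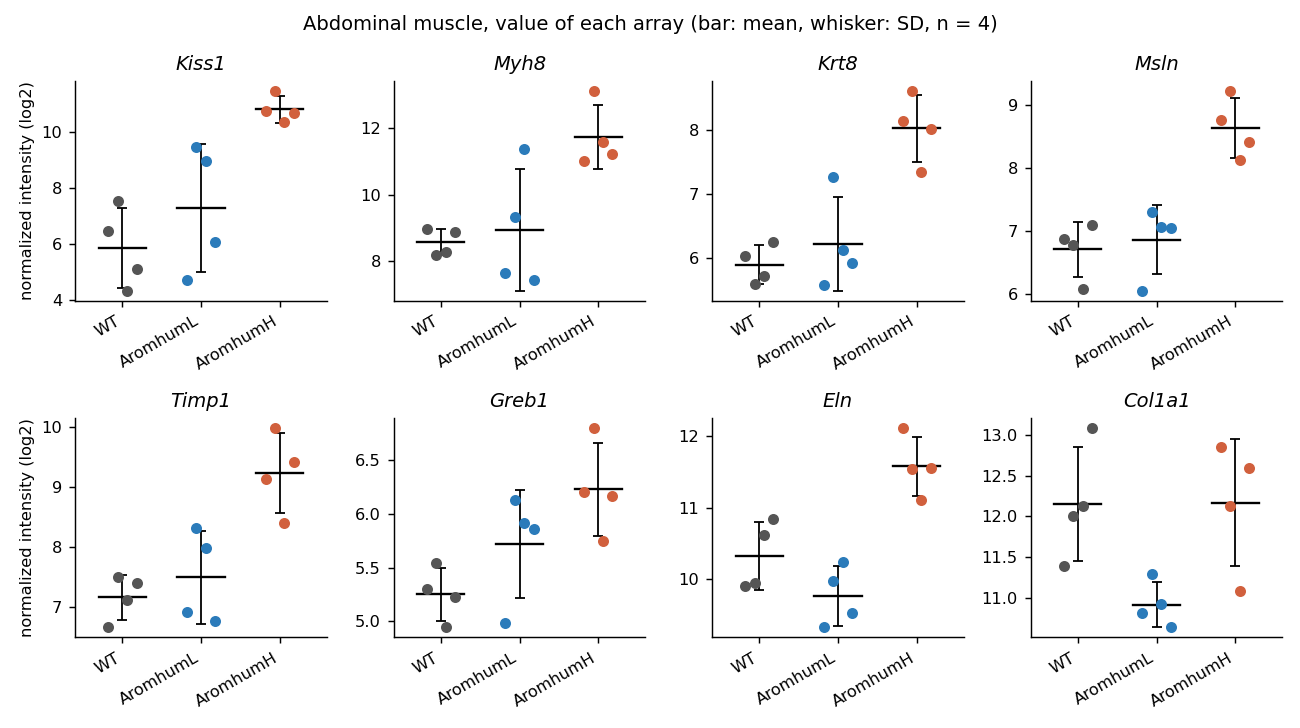
Normalized log2 intensity of 8 genes on each array, by group, with the group mean (bar) and SD (whisker, n = 4). Kiss1, Myh8, Krt8, Msln, Timp1 and Eln were higher on all 4 AromhumH arrays than on all 4 WT arrays, as was Greb1, which missed the threshold, while Col1a1 overlapped between AromhumH and WT.

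Matrix genes moved upward as groups in AromhumH versus WT, with few members past the threshold. All 16 measured collagens lay above 0, with a median log2 change of 0.44, yet 0 rose over all genes and 2 when adjusted over the list alone (camera adjusted p = 0.000185, but adjusted p = 0.469 with an estimated correlation). Col8a1 had the smallest p among them (log2 1.25, adjusted p = 0.0835). The main fibrillar collagens stood at 0.01 for Col1a1 (SE 0.352, adjusted p = 0.993) and 0.31 for Col3a1 (SE 0.319, adjusted p = 0.675, with another probe at 0.16). Of 23 matrix glycoproteins and proteoglycans 1 rose, Eln, which encodes elastin, by 2.38-fold (log2 1.25, with another probe at 0.45), and 4 rose adjusted over the list alone. That list had a camera adjusted p of 0.00574 and an adjusted p = 0.497 with an estimated correlation. Of 20 matrix processing and remodelling enzymes 4 rose, and 7 adjusted over the list alone (camera adjusted p = 0.00131, adjusted p = 0.469 with an estimated correlation). They were Timp1, the collagen lysyl hydroxylase Plod2 (log2 1.28, with 1 of its other probes at 0.09), the lysyl oxidase family member Loxl1 (0.82) and the metalloproteinase Mmp23 (0.80). Mesothelial markers rose on the same arrays (median log2 1.38) and adipocyte markers stood at a median of −0.36, although their mean on AromhumH 1 was the highest of the 12 arrays.

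Muscle and growth genes also shifted. Of 11 measured genes of developmental and regenerative myogenesis, Myh8 and Ncam1, a neural cell adhesion molecule (log2 1.02, with other probes from 0.18 to 0.68), rose, and 6 rose adjusted over the list alone (median 0.49, camera adjusted p = 0.000513, adjusted p = 0.216 with an estimated correlation). All 16 measured cell cycle genes were above 0, with a median of 0.64. Of these 0 rose over all genes and 9 adjusted over the list alone (camera adjusted p = 8.9e-08, adjusted p = 0.291 with an estimated correlation), and the smallest p was that of the mitotic kinase Plk1 (log2 0.64, adjusted p = 0.0628). The IGF axis, with Igf2 at 0.89 (adjusted p = 0.0836), and TGF-beta signalling, with Ltbp3 at 0.53 (adjusted p = 0.136, other probes 0.06 and 0.18), both had a camera adjusted p of 0.0281, and adjusted p = 0.298 and 0.491 with an estimated correlation. Each passed in 9 of 12 fits that left out 1 array (adjusted p up to 0.107 and 0.116). In both lists 0 members rose over all genes, and 2 and 0 adjusted over the list alone. Casq2, the cardiac and slow-fibre calsequestrin, rose (log2 0.85, adjusted p = 0.046), but slow-fibre genes as a list had a camera adjusted p of 0.251. These shifts lay beside the higher mesothelial markers of all 4 AromhumH arrays.

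Oestrogen-responsive genes had a median log2 change of 0.35 over 10 measured members in AromhumH versus WT. Their camera adjusted p was 0.00574, against an adjusted p of 0.232 with an estimated correlation and 0.0341 with fry. None rose over all genes and 1 rose adjusted over the list alone: Greb1, an oestrogen-induced regulator of growth, at 1.97-fold (log2 0.98, SE 0.244, adjusted p = 0.061 over all genes). Mesothelial markers rose on the same arrays. Of 9 androgen-responsive and polyamine genes only Amd2 changed (camera adjusted p = 0.894), and the median over the list was 0.02 while its mean was −0.15. Atrophy and proteolysis genes did not shift in one direction (15 members, camera adjusted p = 0.993). Of these 0 changed over all genes and 2 rose adjusted over the list alone. A fry test for changes in either direction gave an adjusted p of 0.000309, but 16 of 31 lists passed that test in this comparison. The muscle ubiquitin ligases Fbxo32, at −0.71 (SE 0.264, adjusted p = 0.184), and Trim63, at 0.28 (SE 0.329, adjusted p = 0.729), did not pass, nor did the metallothionein Mt1, at 0.62 (adjusted p = 0.0571).

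Energy metabolism moved slightly downward in AromhumH versus WT, with 0 members changed over all genes in each list. The median log2 change was −0.14 over 23 genes of oxidative phosphorylation and the citrate cycle (camera adjusted p = 0.000599, adjusted p = 0.298 with an estimated correlation). Its smallest p was that of Sdhb, a subunit of succinate dehydrogenase, at −0.49 (adjusted p = 0.0836, other probes −0.46 and 0.10), the 1 member that fell adjusted over the list alone. The median was −0.14 over 14 genes of fatty acid oxidation, with Acadl at −0.75 on 1 of its 3 probes and at −0.02 and 0.15 on the others (camera adjusted p of the list 0.00574, adjusted p = 0.469 with an estimated correlation). It was −0.10 over 14 genes of glycolysis and glycogen, with the glycogen synthase Gys1 at −0.77 and its other probe at −0.30 (camera adjusted p = 0.00682, adjusted p = 0.216 with an estimated correlation). Adjusted over the list alone, 0 and 2 of these members fell.

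Markers of other cell types differed on the same arrays. Of 5 mesothelial markers 4 rose in AromhumH versus WT (Msln, Upk1b, Krt19 at 1.06 and Upk3b at 0.97), and 5 adjusted over the list alone (camera adjusted p = 8.9e-08, adjusted p = 0.216 with an estimated correlation). Of 5 epithelial and skin markers 2 rose, Krt8 and Krt18 (log2 1.44), and 3 adjusted over the list alone (camera adjusted p = 0.00438, adjusted p = 0.216 with an estimated correlation). Fibroblast markers had a median of 0.53 over 11 members, with the protease Dpp4 at 0.70 (camera adjusted p = 0.00574, adjusted p = 0.390 with an estimated correlation). Macrophage markers had a median of 0.24 over 11, with Aif1 at 0.39 (camera adjusted p = 0.0281, adjusted p = 0.491 with an estimated correlation, 0.0769 with brightness as a covariate and 0.00732 to 0.0938 on leaving out 1 array). All 9 adipocyte markers were below 0, with the adipokine Adipoq at −1.51 (SE 0.584, camera adjusted p of the list 0.00682, adjusted p = 0.491 with an estimated correlation and 6.38e-08 to 0.0766 on leaving out 1 array). Their mean on AromhumH 1 was 1.07, above every WT array, against −0.85 to −0.46 on the other AromhumH arrays, and without AromhumH 1 the change of Adipoq was −2.34. In these 3 lists 0 members changed over all genes, and 4, 0 and 0 adjusted over the list alone.

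The remaining lists did not shift in AromhumH versus WT. Camera adjusted p-values were 0.0857 for interferon response, 0.44 for Schwann cells, 0.455 for fast-fibre contractile genes, 0.629 for tendon and cartilage and 0.686 for mast cells. They were 0.79 for steroid receptors and enzymes, circadian clock genes, and immediate early and heat shock genes, and 0.894 for endothelial, smooth muscle and pericyte, erythroid and Y-linked genes. The smallest-p members of these lists ran from −0.78 for the steroid enzyme Hsd17b7 (adjusted p = 0.0515) to 0.86 for the tendon transcription factor Scx (adjusted p = 0.0571). The exception was Hspa1b, a heat shock protein, which rose on its brightest probe (log2 0.61) while another probe stood at −0.03.

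**Figure D2:**
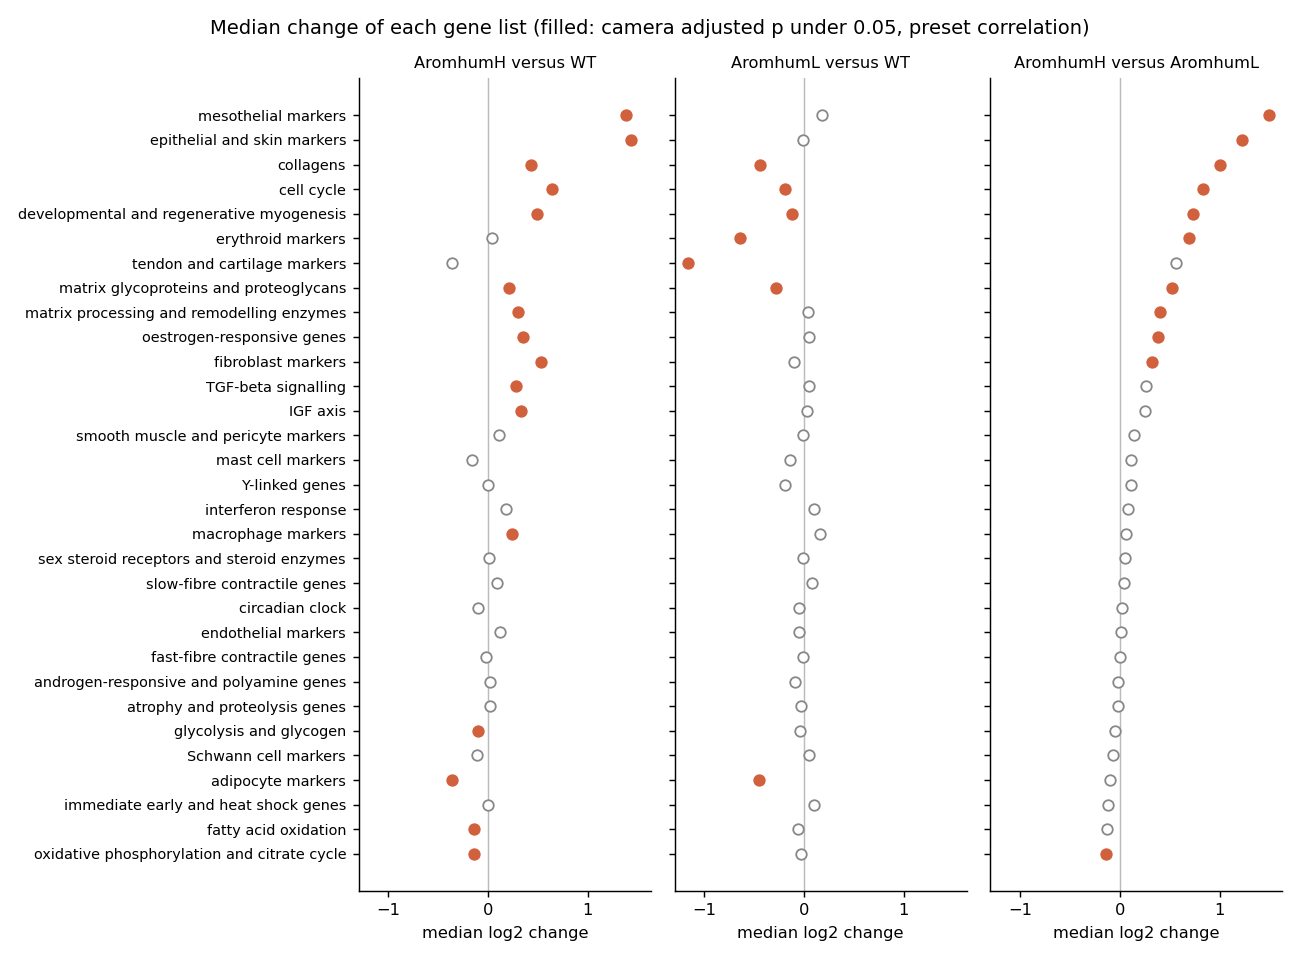
Median log2 change of each of 31 gene lists in the 3 comparisons, filled where camera with a preset correlation gave an adjusted p under 0.05. Mesothelial markers stood at 1.38 in AromhumH versus WT, and collagens at 0.44 in AromhumH versus WT, −0.44 in AromhumL versus WT and 1.00 in AromhumH versus AromhumL. No list passed with an estimated correlation.

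The number of changed genes in AromhumH versus WT depended on single arrays. It was 6 without AromhumH 2, 311 without AromhumH 3, 19 without AromhumH 4, 22 without WT 1, 53 without WT 4, 69 without WT 2 and 76 without AromhumH 1, against 125 with all arrays. It was 76 on the deposited processed values, 36 without the detection filter, 69 with array brightness as a covariate and 0 with the mesothelial marker mean as a covariate, both covariates being chosen after seeing the data and the mesothelial mean itself separating all AromhumH from all WT arrays. With the brightness covariate the median size of these genes' log2 changes was 0.873, against 0.883 without it, and the median SE was 0.173 either way.

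Between AromhumL and WT, where the labels give lower human aromatase expression, 0 of 10575 genes passed (limma, smallest adjusted p = 0.57), and 885 genes had an unadjusted p under 0.05 against 528.8 expected. The 5 genes with the smallest p were Ephx4, an epoxide hydrolase family member, at a log2 change of 0.66, Fam185a at −0.71, Pfkfb3, a regulator of glycolysis, at 0.67, Cog8, a subunit of a Golgi tethering complex, at 0.61, and Nus1, of dolichol synthesis, at 0.57, all at an adjusted p of 0.57. Another Ephx4 probe stood at −0.25. Col1a1 stood at −1.24 (SE 0.352, adjusted p = 0.57), with all 4 AromhumL arrays below all 4 WT arrays, and Col3a1 at −0.66 (SE 0.319, adjusted p = 0.596). With array brightness as a covariate Col3a1 stood at 0.14. Greb1 stood at 0.47 (SE 0.244, adjusted p = 0.605), Fbxo32 at 0.11 and Trim63 at 0.56.

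As groups, 7 lists were lower in AromhumL than in WT by camera, and each had an adjusted p = 0.809 with an estimated correlation and an adjusted p = 0.834 with fry. All 16 collagens were below 0 (median −0.44, camera adjusted p = 2.83e-06), as were 20 of 23 matrix glycoproteins and proteoglycans (median −0.28, camera adjusted p = 0.000143), with Mfap4 at −0.82. Medians were −0.19 for 16 cell cycle genes, with the replication factor Mcm6 at −0.73, and −0.64 for 6 erythroid markers, with the haemoglobin gene Hba-a1 at −0.65 (both camera adjusted p = 0.00166). For 11 myogenesis genes the median was −0.12, with the cardiac alpha-actin Actc1 at −1.06, for 9 adipocyte markers it was −0.45, with Cidec at −1.39, and for 7 tendon and cartilage markers it was −1.16, with Kera at −1.27 (all camera adjusted p = 0.0176). The myogenesis, adipocyte and tendon lists passed in 8, 9 and 8 of 12 fits that left out 1 array. Without the detection filter the adipocyte and tendon lists did not pass (camera adjusted p = 0.259 and 0.307). Over all genes 0 members of the 7 lower lists changed, and adjusted over the list alone 1 did, the collagen Col1a1. The other 24 lists had camera adjusted p-values from 0.119 to 0.989, oestrogen-responsive genes being at 0.855, and their smallest-p members ran from −0.60 for the fibroblast gene Dpt to 0.67 for Bst2. In the oestrogen-responsive list Nrip1, a nuclear receptor corepressor, was detected on 0 of 4 AromhumL arrays and 3 of 4 WT arrays, which places it at least 1.28-fold lower (adjusted p = 0.57). The number of lists was 3 without WT 3 and 4 without WT 4. With array brightness as a covariate, chosen after seeing the data, only erythroid markers stayed lower (adjusted p = 0.00198) and macrophage markers became higher (0.000623, against 0.119 without it), and AromhumL 1 was the dimmest of the 12 arrays, at a mean intensity of 221.6.

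The direct comparison of the lines, AromhumH against AromhumL, gave the most changes in the fit to all arrays without covariates: 425 genes rose and 213 fell of 10575 (limma, adjusted p under 0.05). The order turned with brightness as a covariate, at 0 genes against 69 in AromhumH versus WT. It also turned without AromhumL 1, at 63 genes against 116. Kiss1 was again the largest rise, at 11.4-fold (log2 3.51, SE 0.858, adjusted p = 0.0302), but it spread from 4.72 to 9.49 among AromhumL arrays. Its log2 change was 2.65 without AromhumL 1, 4.25 without AromhumL 2 and 4.07 without AromhumL 3. It passed in 7 of 12 fits that left out 1 array. Among the fits that left out an array of either line, it passed only without AromhumH 3, AromhumL 2 or AromhumL 3. Matrix genes were prominent: Tnc, which encodes tenascin C, rose 4.32-fold (log2 2.11, SE 0.357, adjusted p = 0.00963), Col1a2 3.57-fold (log2 1.84, SE 0.424, adjusted p = 0.0255) and Eln 3.53-fold (log2 1.82, SE 0.258, adjusted p = 0.00727). Krt8 rose 3.50-fold (log2 1.81, SE 0.312, adjusted p = 0.00999). The largest fall was that of Inmt, an indolethylamine N-methyltransferase, whose log2 change was −2.21 (SE 0.585, adjusted p = 0.0401), or 4.62-fold lower.

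Other large rises were those of Emb (log2 2.03), C1qtnf3, a secreted C1q family protein (1.84, other probes 0.92 and 1.45), and the histone H2A genes H2ac22 (2.19), H2ac24 (1.91) and H2ac7 (1.90), whose near-identical copies a probe need not separate. Falls included Amd2 (log2 change −1.64, with another probe at −0.78), Lrrc30 (−1.37), Kcnab1 (−1.36) and Kcng4 (−1.22). The nucleosome-binding protein gene Hmgn5 (−1.25), the small GTPase gene Rab12 (−1.13), Akr1c18, a progesterone-inactivating hydroxysteroid dehydrogenase (−1.11), and Il4i1, an amino acid oxidase gene (−1.07), were lower as well. The immediate early gene Egr3 fell on its brightest probe (by 1.29 on the log2 scale), with another probe at a change of −0.0009.

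Collagens rose together in AromhumH versus AromhumL: 11 of 16 measured members rose, 15 adjusted over the list alone, with a median log2 change of 1.00 (camera adjusted p = 2.09e-10, adjusted p = 0.338 with an estimated correlation). Beside Col1a2, the largest were the network-forming Col8a1 (1.63) and Col8a2 (1.51) and the microfibrillar Col6a2 (1.37). Col1a1 rose 2.38-fold, with overlapping groups (log2 1.25, SE 0.352, adjusted p = 0.0486), and Col3a1 stood at 0.97 (SE 0.319, adjusted p = 0.0774, with another probe at 0.37). With brightness as a covariate the direction of Col3a1 turned, its changes against WT being 0.08 in AromhumH and 0.14 in AromhumL. Of 23 matrix glycoproteins and proteoglycans 6 rose, 11 adjusted over the list alone (median 0.52, camera adjusted p = 1.28e-06, adjusted p = 0.346 with an estimated correlation), among them Tnc, Eln, the proteoglycan Vcan (1.46) and Mfap4 (1.38). Of 20 matrix enzymes and inhibitors 5 rose, among them Timp1 (1.74), Plod2 (1.24, with 1 of its other probes at 0.03), Mmp23 (1.04) and the lysyl oxidase Lox (0.99). Adjusted over the list alone 10 rose and 2 fell (median 0.40, camera adjusted p = 0.00685, adjusted p = 0.571 with an estimated correlation). Second probes of Col8a2, Col6a2, Vcan and Eln stood lower, at 0.33, 0.25, 0.39 and 0.44. On the same arrays mesothelial markers were higher (median fold 2.82) and mean intensity was higher by 75.7.

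Cell cycle and myogenic genes rose as well. Of 16 cell cycle genes 11 rose, and 14 adjusted over the list alone (median 0.83, camera adjusted p = 1.5e-10, adjusted p = 0.320 with an estimated correlation). The largest were Stmn1, a microtubule regulator (1.54), the replication helicase subunits Mcm6 (1.52) and Mcm5 (1.28), and Birc5, which encodes survivin (1.28). Of 11 myogenesis genes 6 rose, and 9 adjusted over the list alone (median 0.73, camera adjusted p = 1.28e-06, adjusted p = 0.109 with an estimated correlation). They included Myh8 (6.89-fold, log2 2.78, SE 0.660), Actc1 (1.54), Ncam1 (1.07, with the lowest of its other probes at 0.31) and Myl4, an embryonic myosin light chain (1.04). For Myh8 the groups overlapped, AromhumL 3 being at 11.37, and its log2 change was 3.60 without that array. Myh8 passed in 7 of 12 fits that left out 1 array. Among the fits that left out an array of either line, it passed only without AromhumH 3, AromhumL 2 or AromhumL 3. These rises also lay beside the higher mesothelial markers and intensity of AromhumH. Igf2, the fetal growth factor, rose (0.98), while the IGF axis as a list had a camera adjusted p of 0.0701.

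**Figure D3:**
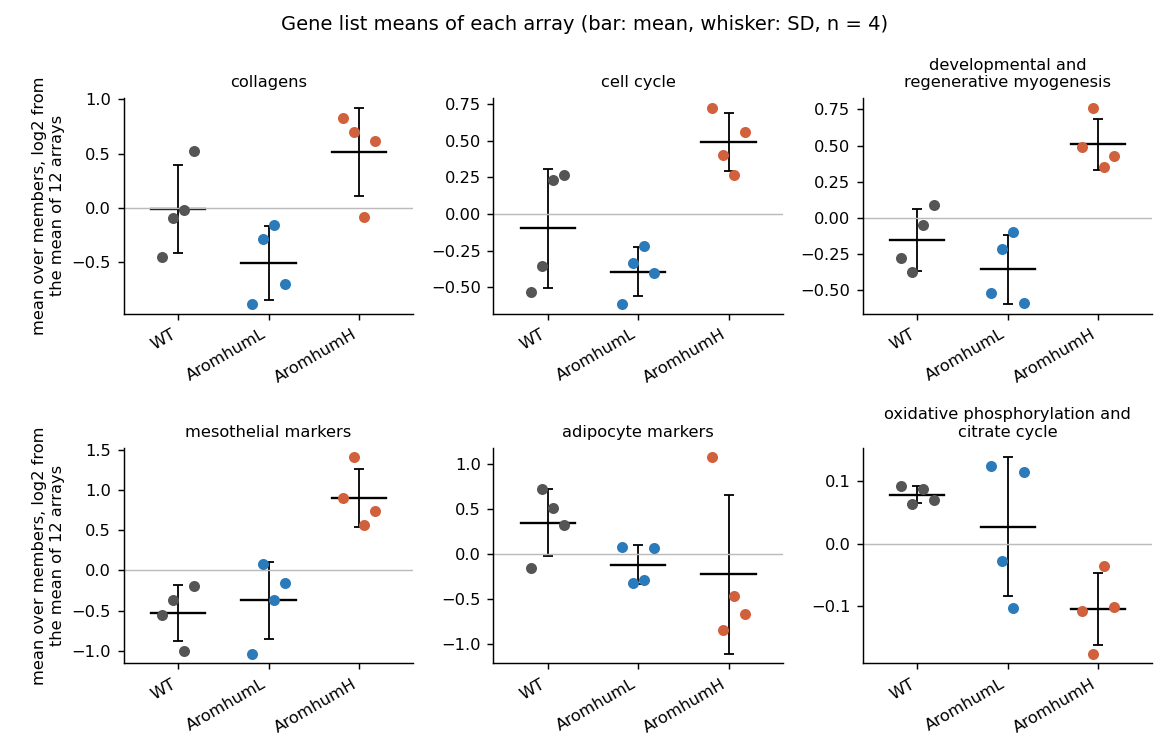
Mean log2 deviation of 6 gene lists on each array from the mean of all 12 arrays, with the group mean (bar) and SD (whisker, n = 4). Collagen means were 0.516 ± 0.407 in AromhumH, −0.00969 ± 0.403 in WT and −0.506 ± 0.341 in AromhumL, with AromhumH 3 at −0.0805 below the other AromhumH arrays.

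Oestrogen-responsive genes had a median of 0.38 in AromhumH versus AromhumL, with 0 of 10 members past the threshold over all genes or adjusted over the list alone. Their camera adjusted p was 0.0187, against an adjusted p of 0.338 with an estimated correlation and 0.0299 with fry. The list did not pass with brightness as a covariate (camera adjusted p = 0.177, with 0.0131 to 0.0738 on leaving out 1 array). Greb1 stood at 0.51 (SE 0.244, adjusted p = 0.205), Ccnd1, which encodes cyclin D1, at 0.55 (adjusted p = 0.101) and Esr1 at 0.61 (SE 0.282, adjusted p = 0.193). Fbxo32 stood at −0.83 (SE 0.264, adjusted p = 0.0722) and Trim63 at −0.28 (adjusted p = 0.636), and Mt1 was the 1 atrophy-list gene that rose (0.66), while 3 rose and 1 fell adjusted over the list alone. In oxidative phosphorylation and the citrate cycle 2 of 23 genes fell, both of the citrate cycle: Idh3a by 0.46, with another probe at 0.23, and Mdh2 by 0.45 on the log2 scale. The same 2 of 23 counted adjusted over the list alone (median −0.14, camera adjusted p = 0.0187, adjusted p = 0.546 with an estimated correlation, 0.0805 with brightness as a covariate and 0.00242 to 0.097 on leaving out 1 array).

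Among cell type markers, 4 of 5 mesothelial genes rose, Msln (1.76), Lrrn4 (1.61), Upk1b (2.82-fold) and Upk3b (0.79), and 5 adjusted over the list alone (camera adjusted p = 2.3e-05, adjusted p = 0.320 with an estimated correlation). Of 5 epithelial and skin markers 3 rose by either adjustment, Krt8, Krt18 (1.22) and the basal keratin Krt14 (1.84), with a camera adjusted p of 0.0184 and an adjusted p = 0.320 with an estimated correlation. This list did not pass without the detection filter (camera adjusted p = 0.183). Of 11 fibroblast markers 2 rose by either adjustment, Thy1 (1.28) and Fap (0.70), with a camera adjusted p of 0.00894 and an adjusted p = 0.365 with an estimated correlation (0.118 with brightness as a covariate and 0.000896 to 0.0407 on leaving out 1 array). Of 6 erythroid markers 0 changed by either adjustment, with Alas2 at 1.07 (median 0.70, camera adjusted p = 0.0187, adjusted p = 0.571 with an estimated correlation). This list passed in 8 of 12 fits that left out 1 array (adjusted p up to 0.174). The other 20 lists had camera adjusted p-values from 0.0701 to 0.999. Members of these that changed were Tgfb3 (0.47), Casq2 (1.06), Scx (0.80), the growth hormone receptor gene Ghr (−0.61), Gys1 (−0.84) and Amd2. The Y-linked Eif2s3y was detected on 0 of 4 AromhumL arrays and was at least 1.07-fold higher in AromhumH (adjusted p = 0.0486). The brightest Hspa1b probe was detected on 4 of 4 AromhumH arrays and 0 of 4 AromhumL arrays, while another probe stood at −0.39.

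The count of 638 changed genes depended on single arrays. It was 63 without AromhumL 1, 96 without AromhumH 4, 113 without AromhumH 2, 118 without AromhumH 1, 145 without AromhumL 4, 359 without AromhumL 2 and 1052 without AromhumH 3. It was 348 on the deposited processed values, 210 without the detection filter, 958 with array weights and 0 with either brightness or the mesothelial marker mean as a covariate, both chosen after seeing the data. With the brightness covariate all 638 genes kept their sign, the median size of their log2 changes going from 0.729 to 0.544 and the median SE from 0.174 to 0.232.

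Side by side, the changes of both lines against WT were correlated across genes at r = 0.134 over 10575 genes, which are not independent replicates. Unchanged groups simulated against the same WT arrays gave 0.497 (0.47 to 0.526 over 100 simulations), and the covariance was 0.00904 against 0.0184 simulated. The jackknife SD of r, from leaving out 1 array at a time, was 0.251, far wider than the simulated range. Whether r lay below the simulated value is therefore not decided. With the WT arrays split 2 and 2, r averaged −0.0871 over 6 assignments (−0.358 to 0.174). Of the 125 genes changed in AromhumH versus WT, 90 (72%) had the same sign in AromhumL versus WT, and on average 68.3% did with split WT arrays (56 to 84%). Genes that rose in AromhumH had a median log2 change of 0.97 there and 0.14 in AromhumL, and genes that fell had −0.78 and −0.04. Between AromhumH versus WT and AromhumH versus AromhumL, which share the AromhumH arrays, 77 rises and 26 falls were common, and the number that unchanged groups sharing those arrays would give was not computed.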

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

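Among the tests reported here, those of skin carry-over, array brightness and the share of muscle fibre RNA were chosen only after the result was seen. A single array stood apart from the other 3 of its group, by the gap to its nearest neighbour over the group's range, in 11 of 231 sets of 4 values (Dixon's ratio, 95% critical value). Chance gives about 1 in 20, or 11.6. AromhumL 1 was dimmer than the other AromhumL arrays (mean intensity 221.6 against 267.6 to 273.9, ratio 0.88). It also had a higher mean of glycolysis and glycogen genes, at 0.13 against 0.01 to 0.03 (0.84). AromhumH 3 had lower means of matrix glycoproteins and proteoglycans, at 0.03 against 0.38 to 0.44 (0.859), and of matrix processing enzymes, at −0.08 against 0.34 to 0.38 (0.909). It also had a lower log2 value of Lrrc15, at 5.19 against 6.76 to 6.94 (0.896), and a higher one of Ephx4, at 5.06 against 4.94 to 4.95 (0.91).

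The other arrays past that ratio stood apart in 1 measure each. AromhumH 4 had a mean of androgen-responsive and polyamine genes of 0.05 against −0.14 to −0.12 (0.944), and WT 1 a mean of fibroblast markers of −0.33 against −0.06 to −0.05 (0.966). Lrrc38 was lower in AromhumL 3 (0.867), Pfkfb3 lower in AromhumH 1 (0.902) and Prr15 higher in WT 4, at 6.58 against 5.20 to 5.33 (0.904).

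The effects of both lines against WT differed from each other, by the direct test of AromhumH against AromhumL, for 638 genes. Array brightness separated these groups as well: 0 genes passed with it as a covariate, and 63 passed without AromhumL 1. Probes without a gene name, which enter no comparison of genes, also changed: 16 of 2740 detected ones (0.584%) in AromhumH versus WT and 120 (4.38%) in AromhumH versus AromhumL, beside 0.781% and 4.80% of probes with a name.

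Splits of the same 8 arrays into 4 and 4 show how often other groupings gave a count as large. The smallest share possible is 1 of 35, and shares were not adjusted for the number of tests. For genes in AromhumH versus WT, 1 of 35 splits, the real one, gave 125 genes, and the highest other gave 26. For AromhumH versus AromhumL, 1 of 35 splits gave 638 genes, and the highest other gave 2. Both argue against chance alone, but the AromhumH versus AromhumL splits do not separate line from array brightness. For gene lists in AromhumH versus WT, 1 of 35 splits gave 16 lists, but the highest other gave 15. Leaving out 1 array gave 12 to 17 lists, so chance is not excluded there. Chance cannot be excluded for the 7 lists of AromhumL versus WT, which 10 of 35 splits matched (highest other 15), or for the 11 lists of AromhumH versus AromhumL, which 11 of 35 splits matched (highest other 14). The count of 0 genes in AromhumL versus WT by limma (885 at an unadjusted p under 0.05) is reached by all 35 splits by construction (highest other 1), so the splits say nothing about chance there.

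Mesothelial and keratin genes were higher in AromhumH than in WT. Whether skin carried over in the dissection was the whole cause is not decided, since the skin keratins Krt10 and Krt14 disagree. The 1 probe of the epidermal keratin Krt10 goes against it. The change of Krt8 exceeded that of Krt10, at −0.126, by a log2 of 2.26 (SE 0.423, 95% interval 1.3 to 3.22). The basal keratin Krt14 goes the other way, at 1.65 in AromhumH versus WT (adjusted p = 0.11) and 1.84 in AromhumH versus AromhumL (adjusted p = 0.0424), so its source stays open. Array brightness as the whole cause is argued against, since the mean change over both lists was 1.19 (SE 0.264) with brightness as a covariate and 1.23 (SE 0.249) without. More mesothelial RNA in the AromhumH samples is a candidate explanation: the mean change of a second set of 6 mesothelial genes was 0.593 (SE 0.103, 95% interval 0.36 to 0.826), against 1.43 for the fixed list. Of these 6 only Gpm6a, at 1.11, and Cldn15, at 0.92 (mean log2 value 7.07 in WT and 7.99 in AromhumH), rose, and Aldh1a2 stood at 0.10. Nkain4, Rspo1 and Aldh1a2 had WT means of 4.785, 4.655 and 4.822, near the detection floor, so their changes may be compressed. Whether such RNA came with the dissection or from a difference in the tissue between the lines was not separated.

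Collagen, matrix and cell cycle genes were higher in AromhumH than in AromhumL, by a mean of 0.825 over 55 genes (SE 0.189). A lower share of muscle fibre RNA that raised all other cell types alike is argued against only by endothelial, smooth muscle and Schwann cell markers. These were chosen after the list results were seen, and the interval does not allow for that choice. The 55 genes exceeded 21 endothelial, smooth muscle and Schwann cell markers by 0.789 (SE 0.223, 95% interval 0.285 to 1.29). Those markers moved by 0.0358 (SE 0.0931). Fibroblast, mesothelial, epithelial and erythroid markers, higher in AromhumH by camera with a preset correlation, were not among the 21. A lower fibre share through more of those cells alone is therefore not decided by this comparison. Array brightness and line cannot be told apart here: with brightness as a covariate the mean difference was 0.465 (SE 0.218, 95% interval −0.0377 to 0.968), and every AromhumL array was dimmer than every AromhumH array. Over the 638 genes, the covariate moved the median size of the log2 difference from 0.729 to 0.544 and the median SE from 0.174 to 0.232. A difference between the lines in aromatase expression stays open and was not tested.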

How the results depend on the processing

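Array brightness and the mesothelial marker mean as covariates were chosen after seeing the data, and unless a reason is given the cause was not tested. AromhumL versus WT had 0 genes by limma in every setting run for it, which leaves out the mesothelial covariate. In AromhumH versus WT, 76 genes changed on the deposited processed values, 36 without a detection filter (19057 genes tested), 69 with the brightness covariate and 0 with the mesothelial covariate, against 125. The brightness covariate left the median size of their log2 changes at 0.873, against 0.883, with a median SE of 0.173 both ways. All 125 genes had the same sign in the first 3 of these settings, and 121 with the mesothelial covariate. In AromhumH versus AromhumL the same 4 settings gave 348, 210, 0 and 0 genes and array weights gave 958, against 638. All 638 had the same sign with the brightness covariate, which enlarged the standard errors, and 626 with the mesothelial covariate. The mesothelial mean separates AromhumH from both other groups and holds changed genes, so its counts of 0 were close to fixed in advance: the median size of the log2 changes went from 0.883 to 0.586 and from 0.729 to 0.566, and the median SE from 0.173 to 0.326 and from 0.174 to 0.306. Leaving out 1 array gave 6 (without AromhumH 2) to 311 genes (without AromhumH 3) in AromhumH versus WT, and 63 (without AromhumL 1) to 1052 (without AromhumH 3) in AromhumH versus AromhumL. Of 30 named genes past the threshold in AromhumH versus WT, 2 passed without AromhumH 2, 7 without AromhumH 4 and 8 without WT 1, and of 57 in AromhumH versus AromhumL 16 passed without AromhumL 1.

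Camera with an estimated correlation left 0 lists in each comparison, and fry gave 7 in AromhumH versus WT, 0 in AromhumL versus WT and 11 in AromhumH versus AromhumL. For AromhumL versus WT the brightness covariate gave 2 lists, 1 of the 7 lower ones (erythroid) and 1 higher (macrophage), and leaving out 1 array gave 3 (without WT 3) to 7. Cell cycle genes there turned upward with the brightness covariate (adjusted p = 0.376, the range over settings being 8.49e-06 to 0.834). Hspa1b reversed in AromhumH versus WT without AromhumH 2 (log2 −0.0167, range on leaving out 1 array −0.0167 to 0.66). In AromhumH versus AromhumL it reversed without AromhumH 2 (−0.37) and without AromhumH 4 (−0.28, range −0.37 to 0.90), because another probe became the brightest. The other named genes past the threshold kept their direction in the settings run for single genes, which leave out the mesothelial covariate. The side by side correlation ran from 0.0313 to 0.287 on leaving out 1 array.

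With the replicate number as a block, the counts were 108, 0 and 466 genes in the 3 comparisons. Arrays of the same number in different groups had a median correlation of 0.0276, and 2 of 12 arrays matched their own number best, so the numbers were not read as pairs. A slide effect was not run, since the slide is not given. Signal over background limits dim genes: the offset of 16 compresses their folds.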

Other observations

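Among the tests in this part, the brightness covariate was chosen only after the result was seen, and the genes in the next 2 paragraphs were named after their values were seen. In AromhumH versus WT, other genes that rose were Krt7, a keratin of simple epithelia, by 3.05-fold (log2 1.61, SE 0.237, adjusted p = 0.00794 by limma), Car12, a membrane carbonic anhydrase (log2 1.67), Dmkn, which encodes dermokine (1.55), and Slpi, a secreted protease inhibitor (1.49). So did the muscle genes Ankrd2 (1.15, SE 0.166, adjusted p = 0.00794) and Csrp3 (0.83, SE 0.140, adjusted p = 0.0145). Clcn1, the chloride channel of skeletal muscle, fell by 0.73 on the log2 scale (adjusted p = 0.0428).

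In AromhumH versus AromhumL, P3h4 (log2 1.01), P3h3 (0.84) and P3h1 (0.62), of the prolyl 3-hydroxylase family, and Crtap, a cartilage-associated protein (0.71), rose, with adjusted p-values by limma from 0.00839 to 0.0473. No list of genes of this kind was tested. Myog, a transcription factor of muscle differentiation (0.89), and Sln, which encodes sarcolipin (0.61), rose as well. Asb10 fell by 1.05, Asb14 fell by 1.02 and Asb2 fell by 0.85 on the log2 scale. They encode members of a family of ubiquitin ligase adaptors.

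Igf2, Dlk1 and Mest, imprinted genes of early growth, were higher in AromhumH than in AromhumL (0.98, 1.70 and 1.64, mean 1.44). A hypothesis is that imprinted genes of early postnatal growth shifted as a set. The mean change of the 5 other measured members was 0.444 (SE 0.162, 95% interval 0.0775 to 0.81). Of these 1 rose, Grb10 at 0.78 (adjusted p = 0.0256), 1 fell, Gnas at −0.77 (adjusted p = 0.0362), and Cdkn1c, Peg3 and Ndn did not pass (adjusted p = 0.0532, 0.168 and 0.0711). With brightness as a covariate the mean was 0.134 (SE 0.186), so the shift may reflect brightness, and the set mean was 0.18 in AromhumH versus WT and −0.264 in AromhumL versus WT.

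The place of each array between the groups was read from the genes that changed in AromhumH. The scale put the WT mean at 0 and the AromhumH mean at 1 over 124 of those genes, leaving out Kiss1. On it AromhumL 1 to 4 stood at −0.158, 0.339, 0.303 and −0.000893. Each WT and AromhumH array was placed with itself left out of its group mean, so on a slightly different scale. AromhumH arrays then spread from 0.706 to 1.29. The log2 values of Kiss1 on AromhumL 1 to 4 were 4.72, 9.49, 8.96 and 6.06, against 10.36 to 11.48 in AromhumH and 4.33 to 7.55 in WT. Mesothelial and epithelial markers were partly among the 124 genes, so they are no separate check of the place. AromhumL 3 and AromhumL 4 had different places but close marker means. Their mean deviation on AromhumL 1 to 4 was −0.931, 0.215, −0.332 and −0.3, against 0.452 to 1.13 in AromhumH and −0.844 to −0.214 in WT.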
